A study of Mus musculus with 4 samples.

How the data were processed

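Gene expression was measured in 4 samples of mouse pancreatic cancer cells from the C57BL/6 strain. Cells named K5 and K6 each gave 1 control sample (DMSO) and 1 sample treated with halofuginone at 100 nM for 24 hours. Halofuginone is an inhibitor of the prolyl-tRNA synthetase activity of the enzyme encoded by Eprs. The sentence of the design that names the comparisons writes F where the sample titles have H, read here as the same samples. What distinguishes K5 from K6 is not given in the sources used here, and they are called lines below. Nothing says that samples came from separate cultures, so p-values concern only the spread between these samples, pooled in part over genes.

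Per the labels' protocols, total RNA was amplified, labelled with Cy3 and hybridised to 1-colour Agilent arrays. Per the file headers, spot intensity was extracted with Agilent Feature Extraction 10.7.1.1, whereas the submitters' processing notes name version 9.5.1.1. The deposited scanner intensity used here is the processed signal, which is background-subtracted and detrended within each array, with dim spots set to a surrogate value, and is not normalized between arrays. The other flags per spot that the authors deposited mark signal well above background, saturation and outliers. The authors' deposited value table was also read. Its 4 columns each have a median intensity of 32.97434 and the same sum, as quantile normalization on a linear scale gives, and each column correlated most closely with its own array. The step that made this table is not given in the sources used here. All 4 arrays lay on 1 slide, so no slide or scan batch could be tested.

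Each array held 59305 spots other than controls, for 56605 probes. No spot was saturated. The share of spots well above background was 47.2% in control K5, 53.1% in halofuginone K5, 48.6% in control K6 and 54.0% in halofuginone K6. The number of arrays limits the precision of every value below.

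Control spots and outlier spots were left out, and spots of one probe were averaged, which left out 301 probes. The main values are log2 of the processed signal minus the 75th percentile of its array. A gene is a gene name in the files, and its value comes from the probe with the highest mean over the 4 arrays. Genes whose probe was well above background on at least 2 arrays were tested, 19093 of 36918. List members among these tested genes are called measured. Of the probes, 32994 had an accession in the reference gene table, for 1535 of which the current symbol differs from the name in the files, and names in the files are used below. Coordinates are those of the probes in the files, on mm9 (NCBI37). Of 6377 tested genes with more than 1 passing probe, 36 had 1 probe at least 2-fold higher and another at least 2-fold lower after halofuginone. Of 503 such genes past the threshold for halofuginone, 35 had a passing probe of opposite sign.

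Halofuginone was compared with control with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the line as a block, and K6 with K5 in the same fit. This fit has 1 residual degree of freedom and 2.97 prior degrees of freedom. Each SE therefore gives more weight to a variance pooled over all genes than to the gene's own. The lowest SE among genes past the threshold for halofuginone was 0.255. P-values were adjusted by Benjamini-Hochberg over all tested genes, with a threshold of 0.05. The numbers 5 and 6 in the sample names pair samples because they name the same cells. Across genes, the K6 minus K5 difference in control samples correlated with that in halofuginone samples at r = 0.50. Within a line there is 1 array per condition, so changes within a line carry no test and are given as values, with counts of genes at least 2-fold higher or lower and well above background on the brighter array. The smallest p of a permutation test of 2 samples against 2 is 0.333, so no permutation test was used.

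Where the probe was not well above background on any array of a group, the fold is given as a bound. It sets the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. The p-value beside a bound comes from the fit on values as read, so it does not test the bound. Gene lists, 21 in number, were tested with camera at a preset correlation of 0.01 and adjusted over all lists, and again with an estimated correlation and with fry. With 1 residual degree of freedom, the estimated correlation rests on 1 residual per gene, and it was -1 and 1 in the lists of 2 genes. The estimated version therefore has little power and cannot decide for or against a shift. Calls with the preset version rest on the assumed 0.01. In the 8 lists that passed with it for halofuginone, the estimates were higher, from 0.12 (tRNA synthetases) to 0.42 (glycolysis and hypoxia). If correlations are that high, the preset p-values are too small. In each line a list's median was set against 10000 random lists of the same size matched on mean expression.

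The fit was tested on simulated data of the same 19093 genes. Noise was drawn independently for each gene from the fit's own variance prior, so shifts shared across an array and dim probes were not simulated. With 4000 changed genes it called 8.55% of those changed by 1 on the log2 scale, 81.4% of those changed by 2 and 95.4% of those changed by 3, with 106 false calls among 2577. With 200 changed genes it called 0 at every size, so a count of 0 from 4 arrays does not show that no gene changed.

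Named genes followed a rule fixed before the data were examined. From genes past the threshold with the same direction in both lines, it took the 12 higher and 12 lower with the largest change in the line that changed less. It also took the 8 highest and 8 lowest of the line comparison, the 5 largest and 5 smallest differences in response among genes well above background on all 4 arrays, Nfe2l2, Keap1, Aldh3a1 and Eprs, and members of the lists. Names that are only clone, locus or accession labels were counted and not named. Some genes that the rule or a list takes are not reported here. Alternatives tried were quantile normalization, median centring, normexp background correction with an offset of 50, the authors' value table, no filter, a filter requiring all 4 arrays, the mean over a gene's probes, eBayes with a trend or robust, no block, a fold threshold, and each array (without the block, which 3 arrays cannot carry) or line left out. A scaling to the 75th percentile of probes detected on all 4 arrays, and list tests with values raised to the highest of the 4 arrays' lowest well-above-background signals, were added after seeing the data.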

Results

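Expression was profiled in K5 and K6 mouse pancreatic cancer cells under control treatment and after halofuginone, with 1 array per line and condition. The series title concerns loss of the transcription factor Nrf2 (gene Nfe2l2) and the enzyme Aldh3a1 in the response to gemcitabine, and the design compares halofuginone with control in each line. Between 47.2% and 54.0% of spots per array were well above background, and both halofuginone arrays had more such spots than both control arrays.

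After halofuginone, 22 of 39 measured genes of the amino acid response and 8 of 20 tRNA synthetases rose. Of the NRF2 targets 10 of 33 fell, of the aldehyde dehydrogenases 6 of 18 (2 rose), of the cholesterol synthesis genes 8 of 21 and of the glycolysis and hypoxia genes 8 of 24. Each of these 6 lists passed as a whole only with the preset correlation, and its shift had a camera adjusted p = 0.89 with an estimated one. With 1 residual degree of freedom the estimated version has little power, so its failure decides neither way. Aldh3a1 fell by 2.53 on the log2 scale (SE 0.31, 2 lines, limma adjusted p = 0.040), with control 5.78-fold above halofuginone. Its log2 changes were -2.88 in K5 and -2.18 in K6, read by a probe on mm9 chromosome 11 from 61031857 to 61031916. Atf5, a transcription factor of the stress response, rose by 4.70 (SE 0.32, adjusted p = 0.036). In the fit over both lines, 740 genes were higher and 970 lower after halofuginone. All 1710 had the same direction in both lines, but this follows from the fit. Its only residual is the difference between the lines' changes, so a gene moving in opposite directions cannot pass. The smallest change among the 1710 genes was 2.80-fold. The calls rest on the paired fit and on the filter, since limma called 0 genes without the block (4492 at an unadjusted p under 0.05) and without a filter (15052). Quantile normalization gave 693 higher and 1021 lower, median centring 1020 and 1445, and the authors' values 691 and 1020. Larger counts came with normexp (2575 and 2853), a trend (2039 and 2161) and the filter on all 4 arrays (1909 and 2103). Scaling on probes detected on all 4 arrays, an alternative added after seeing the data, gave 0 (6481 at an unadjusted p under 0.05).

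Nfe2l2 itself did not pass the test. Its log2 change was 0.34 (SE 0.27, adjusted p = 0.42) at the brightest probe, on chromosome 2 from 75513771 to 75513830. A dimmer probe for another transcript, from 75529291 to 75529350, read 2.56 in K5 and 3.06 in K6, so the gene's probes disagreed. Keap1, whose product targets Nrf2 for degradation, had a log2 change of -0.40 (SE 0.26, adjusted p = 0.34). Eprs, which encodes the target of halofuginone, rose by 1.93 (SE 0.26, adjusted p = 0.042), and its 5 probes read between 1.93 and 2.87.

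Of 39 measured members of the amino acid response list, 22 rose, 0 fell and 17 did not pass; adjusted over the list alone, 35 were higher and 1 was lower. The list's median change was 1.95 in K5 and 2.41 in K6, each at the 100 percentile of random lists (camera adjusted p = 3.31e-15, and adjusted p = 0.89 with an estimated correlation). Trib3, a pseudokinase induced by Atf4, rose by 4.60 (SE 0.45, adjusted p = 0.037). Ddit3, which encodes the transcription factor Chop, rose by 4.38 and Gdf15, a stress-induced cytokine, by 4.25. Asns, asparagine synthetase, rose by 2.53, and Atf4 by 1.95. Ddit4, an inhibitor of mTORC1 signalling, had a log2 change of -1.40 and did not pass (adjusted p = 0.054).

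Among 20 cytosolic tRNA synthetases, 8 rose and 0 fell (15 higher and 1 lower adjusted over the list alone). The median was 1.38 in K5 and 1.49 in K6 (camera adjusted p = 2.69e-06, and adjusted p = 0.89 with an estimated correlation). Aars rose by 2.59 (SE 0.26, adjusted p = 0.037), Yars by 2.34 and Tars by 2.17. Qars, glutaminyl-tRNA synthetase, had a log2 change of -1.48 and did not pass.

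Of 33 measured NRF2 targets, 10 fell, 0 rose and 23 did not pass; adjusted over the list alone, 13 were lower and 2 higher. The median was -0.64 in K5 and -0.91 in K6, at percentiles 0.01 and 0 of random lists (camera adjusted p = 4.18e-04, and adjusted p = 0.89 with an estimated correlation, or 0.20 without a filter). The falls included glutathione S-transferases, which conjugate glutathione to electrophiles. Gsta3 fell by 4.74 (SE 0.78, adjusted p = 0.048), Gsta4 by 4.36, Gstm1 by 3.77 and Gstm3 by 3.71. These genes have close paralogs, so their probes may share signal and single values are uncertain. Ephx1, microsomal epoxide hydrolase, fell by 3.64 (SE 0.30, adjusted p = 0.036), and Cat, catalase, by 1.98. Hmox1 had a log2 change of 0.20 and Slc7a11, the cystine transporter, 1.52, neither past the threshold.

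Of 18 measured aldehyde dehydrogenases, 6 fell and 2 rose (12 lower and 3 higher adjusted over the list alone). The median was -1.21 in K5 and -1.68 in K6, or -1.38 in K6 with dim values raised to 1 common floor (camera adjusted p = 4.32e-04, and adjusted p = 0.89 with an estimated correlation, or 0.13 without a filter). Aldh1a7 fell by 5.29 (SE 0.61, adjusted p = 0.039) with 1 of 2 halofuginone arrays well above background, Aldh1l1 by 4.47, Aldh1a1 by 3.86 and Aldh3b1 by 3.57. The 2 that rose act in folate and proline metabolism. Aldh1l2, the mitochondrial folate enzyme, rose by 4.38 (SE 0.32, adjusted p = 0.036) and Aldh18a1, of proline synthesis, by 2.36. Aldh18a1 is also in the amino acid response list and Aldh3a1 in the NRF2 target list, so these lists overlap. The amino acid response list also shares Slc7a11 with the NRF2 targets and Cars with the tRNA synthetases. The probes of Aldh1a1 and Aldh1a7 both lie on chromosome 19, and as genes of 1 family they may share signal.

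**Figure D1:**
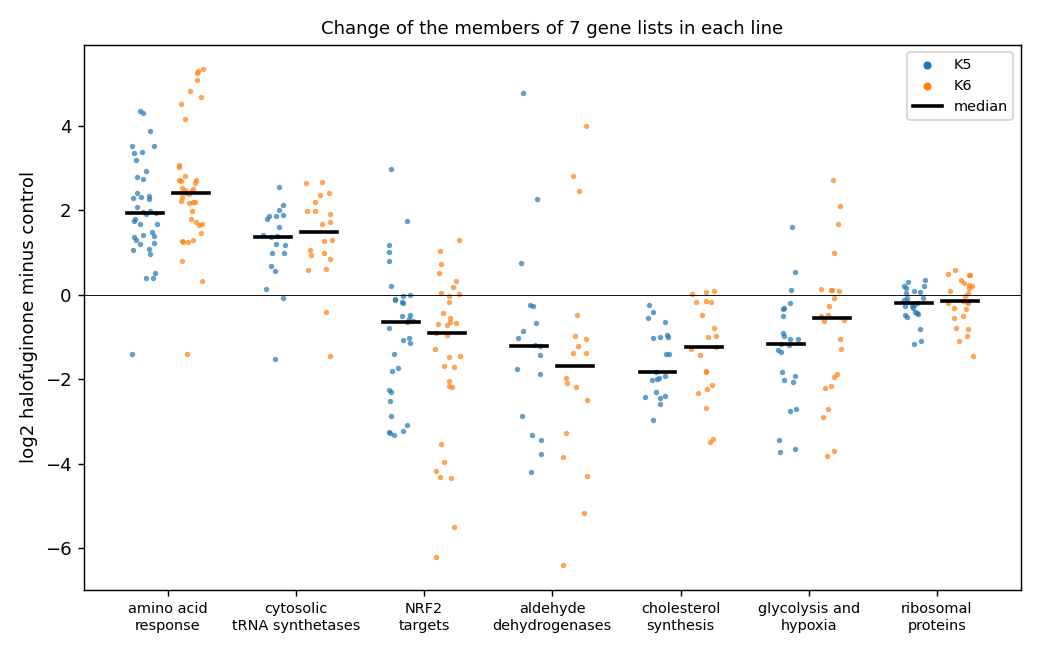
Each point is the log2 change, halofuginone minus control, of 1 member of a gene list in K5 or K6, and bars are medians, with 1 array per line and condition and no error bars. The amino acid response medians are 1.95 in K5 and 2.41 in K6, and the NRF2 target medians are -0.64 and -0.91.

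Of 21 cholesterol synthesis genes, 8 fell and 0 rose (14 lower adjusted over the list alone), with medians of -1.82 in K5 and -1.24 in K6 (camera adjusted p = 5.76e-07, and adjusted p = 0.89 with an estimated correlation). Nsdhl fell by 3.19 (SE 0.28, adjusted p = 0.036), Mvk, mevalonate kinase, by 2.50 and Insig1, a sterol-regulated protein, by 2.32. Of 24 glycolysis and hypoxia genes, 8 fell and 0 rose (10 lower and 1 higher adjusted over the list alone), with medians of -1.17 in K5 and -0.54 in K6 (camera adjusted p = 4.18e-04, and adjusted p = 0.89 with an estimated correlation, or 0.075 without a filter). Egln3, a HIF prolyl hydroxylase, fell by 3.73 with 1 of 2 halofuginone arrays well above background, Slc16a3, the lactate exporter, by 3.57 and Bnip3 by 2.96. Vegfa had a log2 change of 2.15 and did not pass (adjusted p = 0.051).

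The mesenchymal transition list shifted upward (camera adjusted p = 0.019, and adjusted p = 0.89 with an estimated correlation), with 3 of 12 measured members higher and 1 lower (4 and 1 adjusted over the list alone). Its call was lost with the filter on all 4 arrays (adjusted p = 0.051) and without the block (0.11). Snai2 rose by 3.83 (SE 0.26, adjusted p = 0.036), Cdh11 by 2.90 and Zeb2 by 2.47, while S100a4 fell by 2.38. The interferon-stimulated list shifted downward (camera adjusted p = 0.012, and adjusted p = 0.89 with an estimated correlation), with 2 of 20 members lower and 1 higher (5 and 1 adjusted over the list alone), Mx1, at least 3.30-fold higher. Its median was -0.30 in K5 and -1.70 in K6, at percentiles 15.35 and 0 of random lists. In all, 9 of its members were not well above background on all 4 arrays, and with dim values raised to 1 common floor the K6 median was -0.98. Its call was lost with the filter on all 4 arrays (adjusted p = 0.076) and without a filter (0.36). Inflammatory genes went both ways, 4 higher and 2 lower of 22 (5 and 6 adjusted over the list alone), with the list itself not past the threshold (camera adjusted p = 0.85). Ptgs2, cyclooxygenase 2, rose by 4.19 and Csf2 by 3.87, while the chemokine Cxcl5 fell by 5.15.

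The remaining lists did not pass either, and the number in parentheses after each is its camera adjusted p. Adjusted over the list alone, their members past the threshold were as many as over all genes, except 3 higher and 4 lower in the collagen and TGF-beta list, 3 lower immune cell markers and 1 lower endothelial marker. Of 17 genes of gemcitabine transport and metabolism, 0 passed (0.89). Of these 17, 7 were higher in both lines and 7 lower in both. Dck, the kinase that activates gemcitabine, had a log2 change of -0.70 (SE 0.41) and Rrm1 -0.87 (SE 0.32). Nt5c had -1.67, Rrm2b 1.02 and Slc29a1 0.90. Slc28a3 was at least 3.40-fold lower in K5, where only the control array was well above background. In K6 only the halofuginone array was, at -4.80, below the control array's limit of -4.25, so no change is given there. No ER chaperone of 21 passed (0.66), no ribosomal protein gene of 25 (0.40) and no autophagy and lysosome gene of 25 (0.88). In the cell cycle list 1 of 30 passed (0.26), Ccnb2, which fell by 2.53. In the p53 list 2 of 19 rose, Plk2 by 2.83 and Gadd45a by 2.18, and 2 fell (0.099). In the collagen and TGF-beta list 3 of 20 fell (0.88), Col6a1 by 3.25, Thbs1 by 2.13 and Ctgf by 2.09.

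Most markers of other cell types were not among the tested genes, which needed a probe well above background on at least 2 arrays. Of 7 measured immune cell markers 2 fell, Cd14 by 3.38 and Cd68 by 1.79 (0.055, and 0.042 with dim values raised to 1 common floor). This list also passed with normexp (0.042), without a filter (0.025), with the mean over probes (0.040) and without the block (0.042), and had adjusted p = 0.89 with an estimated correlation. With normexp 2 lists not past the threshold in the main setting passed, and without a filter 2, the immune list among them each time. Of 2 endothelial markers Kdr rose by 2.61 with 1 of 2 control arrays well above background (0.73), of 3 acinar markers Cela1 fell by 2.53 (0.49), and of 2 fibroblast and stellate markers Fbln1 fell by 1.67 (0.73). Among 19 epithelial and ductal markers 1 passed (0.57), Muc1, which fell by 3.40.

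The 12 higher genes with the largest change in both lines included several whose control arrays were not well above background. Olfr1265, an olfactory receptor gene, was at least 19.3-fold higher, Cox6a2 at least 16.1-fold, Il6 at least 15.0-fold, Ttc39d at least 11.8-fold, Gareml at least 9.69-fold and Hrk, a BH3-only gene, at least 8.50-fold higher (limma adjusted p from 0.036 to 0.037). Car6 was at least 7.38-fold and Rab39b at least 6.64-fold higher. Vgf rose by 7.39 (SE 0.87, adjusted p = 0.039), Stbd1 by 5.52 and Dusp2, a MAP kinase phosphatase, by 4.54, the last with 1 of 2 control arrays well above background. Among the 12 lower genes, Ttr, transthyretin, was at least 23.6-fold lower, Cst9 at least 21.8-fold, S100g at least 21.0-fold, Fam122c at least 19.9-fold and Ugt2b36 at least 19.6-fold lower. Aldoc, aldolase C, fell by 5.31 (SE 0.26, adjusted p = 0.036), Pdzk1ip1 by 6.36 and Apoc2 by 5.12. C1s2 fell by 7.01, Tm4sf20 by 6.98, Spon2 by 6.37 and Hp, haptoglobin, by 5.04, each with 1 of 2 halofuginone arrays well above background.

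Within each line the changes ran largely the same way. In K5, 2689 genes were at least 2-fold higher and 2851 at least 2-fold lower, and in K6, 3125 and 3134. Both lines shared 1641 higher and 1837 lower genes, against 440 and 468 for independent lists of these sizes. Another 165 genes were at least 2-fold changed in opposite directions. Across genes, which are not independent replicates, the changes correlated at r = 0.69 (Spearman 0.70), and 76.7% had the same sign. These counts have no replicate check.

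**Figure D2:**
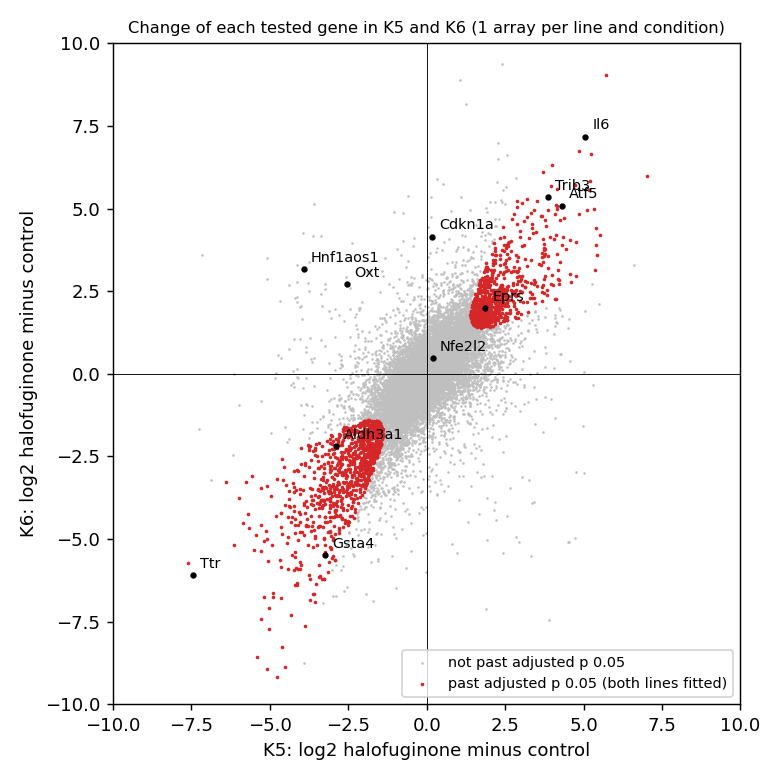
Each point is 1 of 19093 genes, with its log2 change, halofuginone minus control, in K5 on the horizontal axis and in K6 on the vertical axis. The 1710 genes past the threshold lie along the diagonal, since the fit cannot pass a gene that moved in opposite directions. Hnf1aos1 and Oxt lie off it.

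The largest differences in response between lines were not tested, with 1 array per line and condition. Cdkn1a, the cell cycle inhibitor p21, had a log2 change of 0.18 in K5 and 4.15 in K6. Hnf1aos1 had -3.92 and 3.16, Oxt -2.55 and 2.71, Rnf144b -2.92 and 1.103, and Grhl2 -1.47 and 2.47. In the other direction, Dhrs3 had -1.70 in K5 and -6.88 in K6, Lilrb4 -0.03 and -4.03, Vcam1 -2.89 and -6.74, Adam28 0.56 and -3.54, and Kng1 0.46 and -3.32.

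Between lines, with treatment in the fit, Slc16a3, the lactate exporter, was lower in K6 by a log2 difference of -6.22 (SE 0.26, limma adjusted p = 0.045), and Camk2b, a kinase subunit, was higher by 5.06 (SE 0.29, adjusted p = 0.045). In all, 11 genes were higher and 22 lower in K6, 26 of them with a bound, and 2967 had an unadjusted p under 0.05. Rps4l, a ribosomal protein gene copy, was at least 273.2-fold higher in K6 and Ppp2r2c at least 11.0-fold. Dpysl5, Kif1a, Piezo2 and Serpind1 were at least 5.77-fold, 5.84-fold, 5.68-fold and 5.18-fold higher. Mtus2 was at least 90.4-fold lower in K6, Clec2f at least 37.6-fold, Sgce and Prrg1 at least 21.6-fold and 21.5-fold, and St8sia3 at least 15.5-fold lower. Cdh13, a cadherin, was lower by a log2 difference of -6.08, with 1 of 2 K6 arrays well above background. Aldh3a1 had a log2 difference of -1.66 (SE 0.31) and did not pass (adjusted p = 0.15). Of the lists, 9 passed with the preset correlation and 0 with an estimated one, among them glycolysis and hypoxia, lower in K6 (camera adjusted p = 2.56e-05, and adjusted p = 0.79 with an estimated correlation). With fry 1 list passed, the 2 fibroblast and stellate markers, lower in K6 (fry adjusted p = 0.045, and camera adjusted p = 0.79 with an estimated correlation). The counts moved with the processing, from 0 genes with the mean over probes (2892 at an unadjusted p under 0.05), or without the block (798), to 587 higher and 722 lower with normexp.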

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

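All tests in this part except that of the detection limit were chosen after the result was seen.

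Some genes moved in opposite directions in the 2 lines, and none of these differences was tested, since each line has 1 array per condition. The K6 change minus the K5 change was 7.08 for Hnf1aos1, 5.27 for Oxt, 4.02 for Rnf144b and 3.94 for Grhl2. It was -4.10 for Adam28 and -3.78 for Kng1.

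More probes were well above background on the halofuginone arrays, 51.0% against 45.0% in K5 and 52.0% against 46.4% in K6. The lowest signal that counted as well above background was also lower there, at -4.92 and -5.01 on the normalized log2 scale against -4.17 and -4.25 in the controls. With 1 common cut on normalized signal for all arrays, the K5 arrays differed by 0.38 percentage points and the K6 arrays by -0.26, against 0.73 between the 2 control arrays. The excess may therefore come from a lower detection limit on the halofuginone arrays. Folds given as bounds for genes dim in controls depend on the limits of the control arrays, -4.17 and -4.25. Of the 970 lower genes, 153 were not well above background on any halofuginone array. Their bounds depend on the lower limits of those arrays, so bounds for falls and rises are not directly comparable. For single genes the fit took dim values as read, without raising them to a limit. Its p-values concern that unbounded change, so they cannot separate a rise from the detection limit. Of the 740 genes higher after halofuginone, 239 were not well above background on any control array. Whether dim genes without a bound are really expressed under halofuginone stays open.

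The fall of the NRF2 target list may have come from signal shared between glutathione S-transferase paralogs. Without the Gst and Mgst genes, the 26 remaining members had a median of -0.49 in K5 and -0.66 in K6, at percentiles 0.33 and 0.01 of random lists. This argues against paralogs as the whole source of the fall, and 4 of these members passed the threshold. The camera adjusted p was 0.033, and the unadjusted p was 0.25 with an estimated correlation. An effect of halofuginone, the contrast the design names, stays open as a hypothesis, and whether it runs through the Nrf2 protein was not tested.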

How the results depend on the processing

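The scaling to probes detected on all 4 arrays, the raising of dim values to 1 common floor and the NRF2 list without glutathione S-transferases were added after seeing the data. No count, list or named gene reversed, and with normexp 1707 of the 1709 genes past the threshold that it tested kept their sign. Where a cause is not named, the cause was not tested. For halofuginone (740 higher, 970 lower), limma called 2575 and 2853 genes with normexp, 1909 and 2103 with the filter on all 4 arrays (fewer genes tested), 2039 and 2161 with a trend, and 0 and 0 without a filter (15052 at an unadjusted p under 0.05), without the replicate block (4492) and with the added scaling (6481), which moved the median change of all genes by -0.12. With each array left out in turn, without the block and with the lone sample assumed to vary like the others, counts ranged from 0 to 0 (2157 to 4679 at an unadjusted p under 0.05). For K6 against K5 (11 higher, 22 lower), counts were 60 and 88 with quantile normalization, 116 and 182 with median centring, 587 and 722 with normexp, 61 and 91 with the authors' table, 145 and 160 with the filter on all 4 arrays, 134 and 159 with a trend, and 0 and 0 without a filter (3655 at an unadjusted p under 0.05), with the mean over probes (2892), the added scaling (2833), no replicate block (798), and from 0 to 0 with each array left out, again without the block (488 to 1570), so the left-out fits add nothing to it. At 1.5-fold, K5 had 4783 higher and 4861 lower and K6 5298 and 4705; at 3-fold, 1206, 1375, 1411 and 1841. Genes 2-fold higher in K5 were 1620 with normexp and 1720 with the filter on all 4 arrays. The correlation of changes was 0.75 with normexp, 0.48 without a filter, 0.77 with the filter on all 4 arrays and 0.68 with the mean over probes. Of the lists, 8 passed, 9 with the common floor, between 6 and 10 over the scalings, filters and no block, and 0 with an estimated correlation or fry, where adjusted p was 0.89 and 0.21 for medians of -0.995 (NRF2 targets), -1.44 (aldehyde dehydrogenases), 2.14 (amino acid response) and 1.39 (tRNA synthetases). Without a filter the first 2 had medians of -1.01 (adjusted p = 0.20) and -1.25 (0.13). Folds are bounds where a probe was dim on every array of a group, and log2 values of probes dim on some arrays are less certain.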

Other observations

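The test on the liver and foregut list was chosen after the result was seen, since 2 of its members, Tff2 among them, had been looked at and the idea came from the strongest falls. The test on small nucleolar RNA host genes was set before its values were seen. These were the 2 lists tried.

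Some genes usually active in liver and foregut fell. Fgb, a fibrinogen chain, was at least 19.2-fold lower (limma adjusted p = 0.037), and the trefoil factors Tff2 and Tff3 fell by 5.16 and 4.25, Tff2 with 1 of 2 halofuginone arrays well above background. Of 25 measured genes of a liver and foregut list that leaves out the 12 strongest falls, 10 fell and 0 rose. Serpina1a, Serpina1b and Serpina1c fell too, and being near-identical copies they may count 1 signal several times. The median was -1.25 in K5 and -1.45 in K6, at percentile 0 of random lists in both lines, and the same medians and percentiles held over 23 genes without the 2 members looked at earlier. They held too with dim values raised to 1 common floor. A general fall of such a gene programme is a hypothesis that these values are consistent with (camera adjusted p = 5.36e-06 over the 2 lists, and adjusted p = 0.33 with an estimated correlation). Among transcription factors of the list, Hnf4a had a log2 change of -1.35 (adjusted p = 0.057) and Foxa1 one of -0.33, neither past the threshold.

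Host genes of small nucleolar RNAs are known targets of nonsense-mediated decay, which needs translation, and may rise when translation is slowed. Of 13 measured, 2 rose and 1 fell. Snhg5 rose by 2.30 (SE 0.31, adjusted p = 0.043), Snhg18 fell by 1.98 with 1 of 2 halofuginone arrays well above background, and Gas5 had a log2 change of 1.84 (adjusted p = 0.051). In both lines 8 were higher, and 1 was lower in both. The list had a camera adjusted p = 0.023 over the 2 lists, and adjusted p = 0.33 with an estimated correlation. The median lay at percentile 99.91 of random lists in K5 and 67.93 in K6, so the prediction for both lines was met in K5 alone and the question stays open. The difference between lines was not tested.

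Fth1, ferritin heavy chain, stood apart on 1 array, with a normalized log2 signal of 4.28 in control K5 against 7.26 in halofuginone K5, 7.28 in control K6 and 7.12 in halofuginone K6, from 1 probe.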
